A study of Salmonella enterica subsp. enterica serovar Newport with 9 samples.

How the data were processed

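Total RNA from 9 samples was depleted of rRNA and made into strand-marked libraries by incorporating dUTP in the second strand, which was digested before amplification, and the libraries were sequenced as DNA nanoballs on a DNBSEQ instrument, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, StringTie, Cufflinks, Bowtie2, RSEM and DESeq2 1.20.0 without saying which step each served. The genome build and annotation are not given in the sources used here, nor is the strand setting of the counting.

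The deposited files are RSEM tables with 1 row per gene, and per the file headers they give expected counts, FPKM, TPM and gene length. The expected counts are estimates by the authors that need not be whole numbers, and 98.0% of the listed values were whole within 0.001. The FPKM and TPM values deposited by the authors are scaled for gene length and depth. FPKM served only as an alternative and TPM was not tested. The other deposited column used was gene length, which was a multiple of 3 in 99.2% of models and is called coding length. The tables list only genes with a value above 0, so an absent gene was taken as 0. Expected counts that RSEM divides between near-identical genes are uncertain for each of them, and 32 of the tested genes had fractional values in some library.

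Groups and replicate numbers were taken from the sample titles. The labels of the 3 control samples conflict, because their treatment and tissue fields describe uninoculated onion whereas the titles and the protocol text describe cultures of Salmonella. They are called cultures here, following the titles and the protocol text. All RNA counted in the onion libraries is RNA assigned to bacterial genes, and whether part of it came from other organisms was not tested. The total amount of RNA in those samples, plant RNA included, was not analysed here.

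Expected counts were rounded to whole numbers. CPM is the rounded count scaled to a library total of 1000000 rounded counts. Genes were kept with filterByExpr of edgeR 4.0.16 at a minimum count of 10, which corresponded to 111 CPM at the median library and left 1966 of 4550 genes. Counts were scaled by TMM and tested in R 4.3.3 with edgeR's robust quasi-likelihood fit over all 9 libraries without a replicate block, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors were computed from the fold change and its F statistic. The comparisons were day 1 onion against culture, day 7 onion against culture, and day 7 onion against day 1 onion. The test, its samples and most alternatives were fixed before the data were examined. Alternatives used limma 3.58.1, DESeq2 1.42.0, other scaling factors and filters, a replicate block, thinned counts, a minimum fold change, and each library left out in turn.

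None of the identifiers matched the reference table of 4717 genes that was supplied, so 0 genes carry a name. Gene lists and named genes that had been fixed beforehand could not be evaluated, and neither could the alternative without rRNA, tRNA and ribosomal protein genes. Under the fixed rule, identifiers were ranked by absolute log2 fold change among genes with an adjusted p below 0.05, no overlap in CPM between the groups compared and at least 10 counts in at least 2 of 3 libraries of the higher group, with up to 2 higher and 2 lower per comparison. The 2 that rose were the same on both days. Those that fell are printed for day 1, and the 2 chosen for day 7 are left without identifiers, so that at most 2 of each kind are printed. Those 2 had 376 and 325 CPM in culture and 0 counts in all day 7 libraries, at least 21.1-fold and 18.2-fold lower.

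Locus numbers were read from the identifiers, as an order of genes only. A run was at least 4 tested genes with consecutive locus numbers called in the same direction, and its number was compared with 10000 shuffles of the calls. Correlations between neighbours were compared with 2000 shuffles. Shared controls were examined with 20 simulations of unchanged groups. A fold against a group at 0 is a bound computed from 3 counts over the group.

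To see whether any 2 libraries were repeated sequencing of 1 library, counts were compared within groups. The chi-square statistic per degree of freedom ranged from 12.4 to 16.9 between cultures, from 6.28 to 38.7 between day 1 libraries and from 2.94 to 3.93 between day 7 libraries, so none were merged. Values above 1 do not show that the samples, the cultures among them, were independent.

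The procedure was tested on simulated data for the 1966 genes with 200 changed genes at the real library sizes, in 20 simulations per comparison. With 1 spread for all groups, false calls averaged 3.71%, 3.97% and 4.29% of all calls in the comparisons of day 1 with culture, day 7 with culture and day 7 with day 1. With each group's own spread they averaged 19.5%, 0.254% and 10.2%. In the latter setting, genes raised by 2 on the log2 scale were recovered in 81.4%, 65.4% and 46.3% of cases and genes lowered by 2 in 63.4%, 30.1% and 32.5%. For changes of 4, the recovered shares were 99.9%, 99.9% and 99.8% of genes raised and 94.5%, 71.8% and 65.3% of genes lowered.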

Results

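Gene expression of Salmonella enterica serovar Newport, a foodborne pathogen represented here by a mixture of strains from an onion-linked outbreak, was measured by RNA sequencing in 9 libraries. Of these, 3 came from cultures of the bacterium, 3 from inoculated onion bulbs at day 1 and 3 from inoculated bulbs at day 7. The bulbs were independent according to the protocol text. Nothing states whether the 3 cultures were separate, so the p-values measure the spread between these samples, which may be partly technical in the cultures. The depth differed widely between groups. Cultures held 10986030 to 11309611 counts on bacterial genes, day 1 onion libraries 179827, 78251 and 83131, and day 7 onion libraries 67487, 90180 and 10641. The mean culture total was 97.7 times the mean day 1 total and 198 times the mean day 7 total. A count of 0 therefore allowed up to 0.273 CPM (counts scaled to a library total of 1000000) in the shallowest culture, and up to 282 CPM in day 7 replicate 3. These limits and the floors given later are 3 counts and cover counting error only.

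Of 4550 genes with a value in any library, 1966 were abundant enough to be tested. The files identify genes by locus identifiers alone and do not pair them with names, so genes are described by their measured behaviour, their coding length and their neighbours in locus number. At most 2 identifiers that rose and 2 that fell are given.

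The cultures resembled each other closely, with Spearman correlations of log2 CPM across the tested genes between 0.991 and 0.993. Among the onion libraries other than day 1 replicate 1, the 10 pairwise correlations ranged from 0.649 to 0.862. Day 1 replicate 1 stood apart, at 0.381 to 0.462 with the other 5 onion libraries and at 0.412 to 0.414 with the cultures. Day 7 replicate 3, the shallowest library, stood apart to a lesser degree, at 0.649 to 0.696 with the other 4, against 0.755 to 0.862 among those 4. Depth limits these values. With the onion libraries thinned to 10641 counts, the 10 pairs lay between 0.542 and 0.666 over 20 draws. The lower values of day 7 replicate 3 are therefore no evidence of another profile, and the far deeper cultures are not directly comparable. These correlations are across genes, which are not independent replicates. The biological coefficient of variation was 7.33% in cultures, 66.1% in day 1 onion libraries and 29.8% in day 7 onion libraries. Without replicate 1 the day 1 value was 32.3%, and without replicate 3 the day 7 value was 23.4%. Values below with a library left out are for the same 1966 genes.

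**Figure D1:**
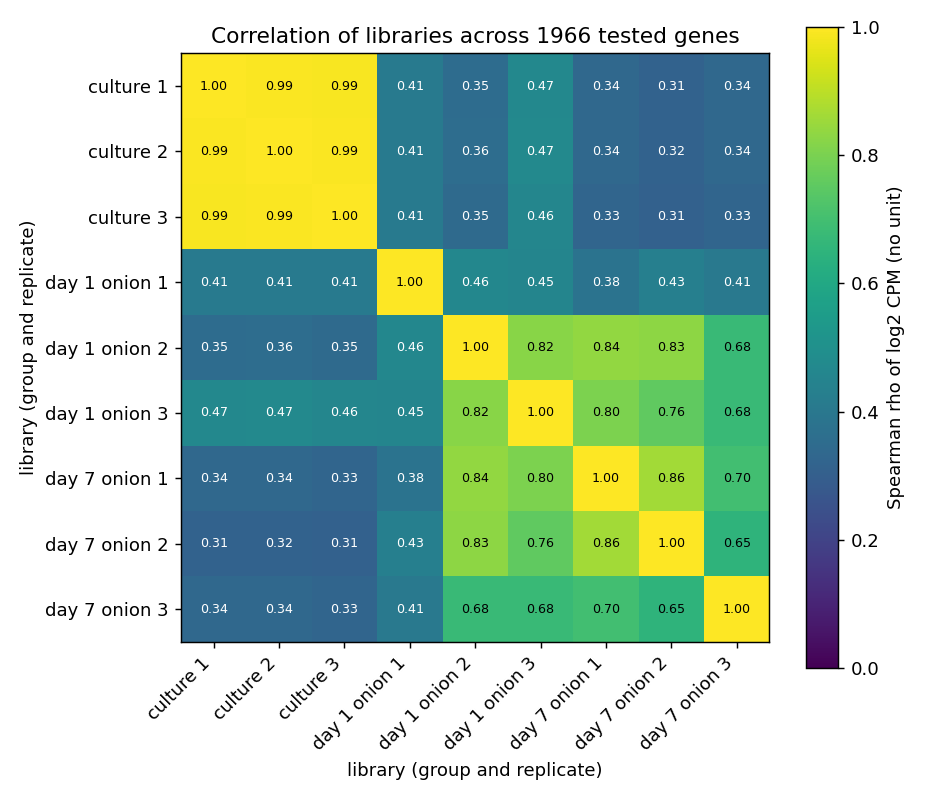
Spearman correlation of log2 CPM across the 1966 tested genes for each pair of the 9 libraries, with rows and columns ordered by group and replicate and colour from 0 to 1. The 3 cultures form a block of at least 0.991, and day 1 onion replicate 1 lies at or below 0.462 with every other library. Depth was far greater in the cultures, and thinning lowered the correlations between onion libraries.

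The first comparison asked how the transcriptome in onion tissue at day 1 differed from that in culture. The most abundant transcripts differed in part, since the lists of the 100 most abundant genes of culture and of day 1 onion shared 48 genes. The 100 most abundant genes of the cultures held 37.5% ± 0.209 of the counts there (SD, n = 3) and 23.4% ± 1.00 at day 1 (SD, n = 3). Of these 100 genes, 39 fell, 2 rose and 59 did not pass the test, while 61 fell and 7 rose without day 1 replicate 1. The 100 most abundant genes of day 1 onion went the other way, with 24.5% ± 0.200 of the counts in culture and 36.4% ± 3.26 at day 1 (SD, n = 3), and 32 of them rose and 2 fell. Without culture replicate 1, 2 or 3, 16, 15 or 15 of them rose, and without day 1 replicate 1 42 rose and 14 fell. A list chosen for being highest in 1 condition is expected to hold a lower share in another, so neither direction is evidence by itself, and the same holds for genes chosen as scarce. The 1340 genes below 20 CPM in culture held 0.940% ± 0.0254 of the counts there and 2.53% ± 0.296 at day 1 (SD, n = 3). Of these genes 32 could be tested, and all 32 rose, or 20 without day 1 replicate 2, but the filter admits a gene this scarce in culture only where it is abundant in onion, so that count is not evidence of a direction for the group. The exact two-sided permutation p was 0.1 for each of these shares, the smallest that 3 against 3 libraries allow. These gene groups were defined after the data were seen.

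In all, 748 genes changed at day 1 by edgeR's quasi-likelihood test at an adjusted p below 0.05, with 364 higher and 384 lower than in culture. The median log2 fold change was 1.95 among the genes that rose and fell by 1.96 among those that fell, with genes at 0 set at their bound. The libraries of the 2 groups did not overlap in 1012 genes, or 51.5% of those tested. Chance would give 10% only with the same spread in both groups. The biological coefficient of variation was 7.33% in cultures and 66.1% in day 1 libraries, so 10% is not a fair reference. L3P16_000352, with a coding length of 252 bases, had 7.01 ± 1.38 CPM in culture and 3687 ± 3724 CPM at day 1 (SD, n = 3), a log2 fold change of 8.94 with a standard error of 1.57 and an edgeR adjusted p of 0.00184. L3P16_000994, of 1680 coding bases, rose by a log2 fold change of 7.93 with a standard error of 1.31 and an edgeR adjusted p of 0.00140. Both rises rested mainly on replicates 2 and 3. Replicate 1 held 2 counts of L3P16_000352, against 281 and 620 in the others, and 15 counts of L3P16_000994, against 602 and 699. In replicate 1 these were 11.1 and 83.4 CPM, above the highest culture at 8.58 and 23.3 CPM. For L3P16_000352 that difference is within counting error, since 3 counts in this library are 16.7 CPM. With FPKM on the log2 scale the adjusted p by limma was 0.0874 and 0.0981 for L3P16_000352 at pseudocounts of 1 and 0.1, and 0.0483 and 0.0519 for L3P16_000994.

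L3P16_001631 and L3P16_001630, of 1005 and 933 coding bases, fell to 0 counts in every onion library. Their culture levels were 299 ± 58.2 and 234 ± 48.8 CPM (SD, n = 3), so with a floor of 3 counts over the day 1 group they were at least 34.0-fold and 26.6-fold lower. The edgeR adjusted p was 0.000766 and 0.00155. They belong to a run of 4 consecutive locus numbers whose summed level was 1061 ± 225 CPM in culture and 15.7 ± 5.69 CPM at day 1 (SD, n = 3).

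The number of genes called at day 1 depended on the cultures, since leaving out culture replicate 1, 2 or 3 gave 397, 387 or 386 genes. Of these, 162, 156 or 156 rose and 235, 231 or 230 fell. With each group's own spread and 200 changed genes simulated, 19.5% of edgeR calls for this comparison were false, against a nominal 5%. Over 20 simulations of 1966 genes, a mean of 41.3 calls were false among a mean of 210.9. The false share depends on how many genes truly change, so it does not carry over to the 748 genes called here.

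The second comparison asked the same of onion tissue at day 7. The 100 most abundant culture genes held 21.9% ± 0.998 of the counts at day 7 (SD, n = 3) against 37.5% ± 0.209 in culture (SD, n = 3), with 44 members lower, 3 higher and 53 not passing the test, and with 66 lower and 7 higher without day 1 replicate 1. The 100 most abundant genes of day 7 onion held 22.5% ± 0.271 in culture and 39.4% ± 3.55 at day 7 (SD, n = 3), and 40 of them rose and 1 fell. Without day 1 replicate 1, 53 of this list rose and 12 fell. It shared 45 genes with the culture list and 75 with the day 1 list. The 1340 genes scarce in culture held 2.64% ± 0.0632 (SD, n = 3), and 31 of the 32 members that passed the filter rose. The exact two-sided permutation p was again 0.1 for each share. Short genes, with a coding length under 300 bases, held 3.71% ± 0.398 of the counts in culture, 4.77% ± 1.64 at day 1 and 5.84% ± 0.748 at day 7 (SD, n = 3), with a permutation p of 0.4 at day 1 and 0.1 at day 7. Long genes, of 2000 bases or more, held 14.8% ± 0.250, 12.0% ± 2.47 and 10.7% ± 1.04 (SD, n = 3), with a permutation p of 0.2 and 0.1. Day 1 replicate 1 held 3.02% in short genes, below every culture (3.39% to 4.16%), and 14.8% in long genes, within the culture range, while day 1 replicates 2 and 3 held 5.05% and 6.25% in short and 10.4% and 10.7% in long genes. Of the 84 short genes tested, 26 rose and 9 fell at day 7, while 16 rose and 5 fell without day 7 replicate 1. The number that fell was 4 without day 7 replicate 2, 5 without culture replicate 1 or 2 and 17 without day 1 replicate 1, and 17 rose without culture replicate 3. RNA integrity was not examined, so a technical source of a shift with length was not tested.

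At day 7, 674 genes changed by the edgeR test, 299 of them higher and 375 lower than in culture. The median log2 fold change was 2.19 among the genes that rose and fell by 2.51 among those that fell, with the 12 genes at 0 in all 3 libraries set at their bound. The same 2 genes led the rises. L3P16_000352 reached 4415 ± 134 CPM (SD, n = 3), a log2 fold change of 9.20 with a standard error of 1.59 and an edgeR adjusted p of 0.00168. L3P16_000994 reached 7109 ± 1399 CPM (SD, n = 3) from 21.03 ± 2.48 CPM in culture, with a log2 fold change of 8.33, a standard error of 1.34 and an edgeR adjusted p of 0.00129. The run of 4 genes that holds L3P16_001630 and L3P16_001631 had no counts in any day 7 library, which put its sum at least 59.5-fold below culture for a floor of 3 counts over the day 7 group. A different run of 6 genes went from 10881 ± 557 CPM in culture to 1180 ± 774 CPM at day 1 and 186 ± 52.0 CPM at day 7 (SD, n = 3), and all 6 members fell at day 7.

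Single libraries moved the day 7 count by more than 1.5 times. It was 410 without day 7 replicate 1, 413 without day 7 replicate 2, 449 and 440 without culture replicates 2 and 3, and 1121 without day 1 replicate 1. Without day 7 replicate 1 or 2, 166 or 173 genes rose and 244 or 240 fell. Without culture replicate 1, 2 or 3, 185, 177 or 174 rose and 280, 272 or 266 fell. Without day 1 replicate 1, 531 rose and 590 fell. Fitting the 2 groups alone gave 1166 of the same 1966 genes, and 638 for day 1 against culture. DESeq2 gave 927 at day 7 and 1023 at day 1. Which day had more genes called thus depended on the setting, so 674 against 748 does not show fewer changes at day 7.

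Fold changes of genes with neighbouring locus numbers were correlated in all 3 comparisons. The Spearman correlation of log2 fold changes between genes 1 locus number apart was 0.463 over 1149 pairs at day 1 and 0.450 at day 7, and it was 0.0112 and 0.000370 at a distance of 20. For day 7 against day 1, where no gene was called, it was 0.422 at a distance of 1, so the pattern is not particular to the change from culture. With 1 library left out, that value ranged from 0.276 to 0.456. With all libraries, the permutation p at a distance of 1 was 5e-04 in each comparison, the smallest that 2000 permutations can give. Runs of at least 4 consecutive locus numbers called in the same direction held 84 genes at day 1, in 8 rising and 8 falling runs, and 113 genes at day 7, in 8 rising and 15 falling runs. Shuffled calls gave at most 34 and 23 genes in such runs, with a permutation p of 1e-04, the smallest that 10000 permutations can give. The size of the runs depended on single libraries. At day 1 they held 40, 35 and 39 genes without each culture in turn. At day 7 they held 61 and 39 genes without day 7 replicates 1 and 2 and 60, 52 and 51 without each culture. The longest run held 10 genes and rose in both comparisons. Its summed level was 362 ± 33.6 CPM in culture, 3267 ± 2627 CPM at day 1 and 5343 ± 667 CPM at day 7 (SD, n = 3). Day 1 replicate 1 held 272 CPM of it, below the 323 to 382 CPM of the cultures, so its day 1 rise rested on replicates 2 and 3. In 4 of the 8 rising day 1 runs that library lay at or below the highest culture. A rising run of 5 genes that begins at L3P16_000994 summed to 207 ± 12.8 CPM in culture, 11685 ± 10046 CPM at day 1 and 13926 ± 2962 CPM at day 7 (SD, n = 3). Day 1 replicate 1 held 167 CPM of this run, below every culture, while the other onion libraries held 10525 to 18633 CPM.

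**Figure D2:**
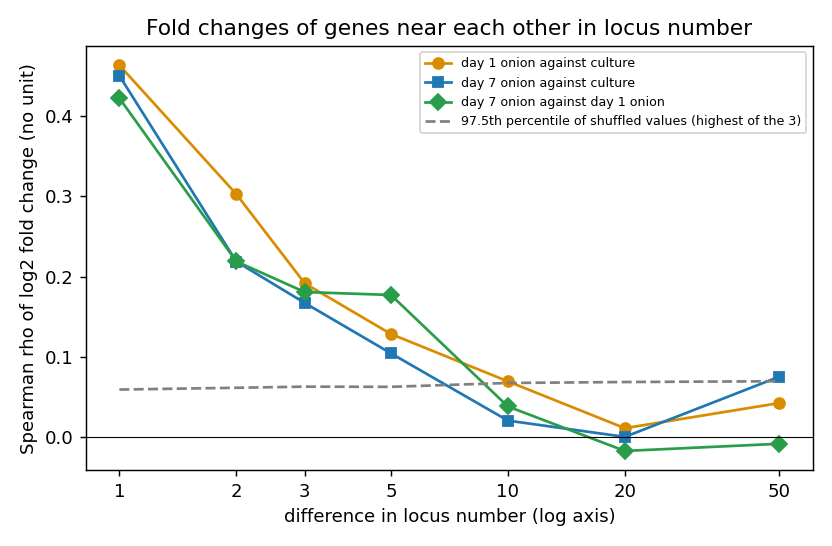
Spearman correlation of log2 fold changes (vertical axis, no unit) between genes a given difference in locus number apart (horizontal log axis), with 1 line per comparison and a dashed line at the upper end of the central 95% of shuffled values, the highest of the 3 comparisons. All 3 lines start above 0.42 at a distance of 1 and lie at or below 0.0112 at a distance of 20.

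The third comparison tested whether the 2 days in onion differed. No gene passed the edgeR test, with a smallest adjusted p of 0.187, although 265 of 1966 genes had an unadjusted p below 0.05. DESeq2 called 120 of the same 1966 genes, 43 higher and 77 lower at day 7, and limma on log2 FPKM called 4. The edgeR count was 16 without day 1 replicate 1, with 4 genes higher and 12 lower at day 7, and 2 without day 1 replicate 2, both higher. The median standard error of the log2 fold change was 0.53. In simulated data of this comparison with each group's own spread, the edgeR test recovered 46.3% of genes raised and 32.5% of genes lowered by 2 on the log2 scale among 1966 genes, and 99.8% and 65.3% for changes of 4. With 1 spread for all groups at the same depth it recovered 63.5% and 44.1% for changes of 2. The share of the 100 most abundant culture genes was 23.4% ± 1.00 at day 1 and 21.9% ± 0.998 at day 7 (SD, n = 3), with an exact two-sided permutation p of 0.2.

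The 2 days were then set side by side through their shared cultures. Of the genes that rose, 209 rose on both days, where independent lists would share 55.4. Of those that fell, 299 fell on both days, against 73.2 for independent lists. Unchanged groups simulated against the same cultures gave no calls at day 7, so their overlap of 0 is fixed and carries no information. No gene was called in opposite directions. The fold changes of the 2 days had a correlation of 0.844 across genes, against a simulated mean of 0.0588, and a covariance of 3.05, against a simulated mean of 0.0264. The 3 cultures are too few to be split so that each part keeps 2 libraries. In the simulations, the correlation reached at most 0.167 and the covariance at most 0.0881. These values argue against chance spread between the shared cultures as the source of most of the correlation and covariance. They cannot separate a shared onion response from a profile particular to these cultures, which any 2 other groups set against them would share. The simulated values would be too low if the spread between the cultures is only technical. Part of the overlap may still come from sharing the cultures.

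The libraries were also compared over the genes called at day 7. The 299 genes that rose had a median log2 ratio to culture of 1.93, 1.96 and 1.58 in day 7 replicates 1, 2 and 3, and of 1.87 and 1.58 in day 1 replicates 2 and 3. In day 1 replicate 1 the median was 0.43, and 34.4% of these genes were more than 2-fold above culture, compared with 80.9% and 71.2% in the other day 1 libraries. The 375 genes that fell showed no such gap. Their median was -1.71 in day 1 replicate 1, -2.03 and -1.76 in day 1 replicates 2 and 3, and -2.30, -2.28 and -2.89 in the day 7 libraries. The ratios were taken after adding 20 CPM, and the genes were chosen on the day 7 libraries, so the day 7 values are not independent of that choice.

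**Figure D3:**
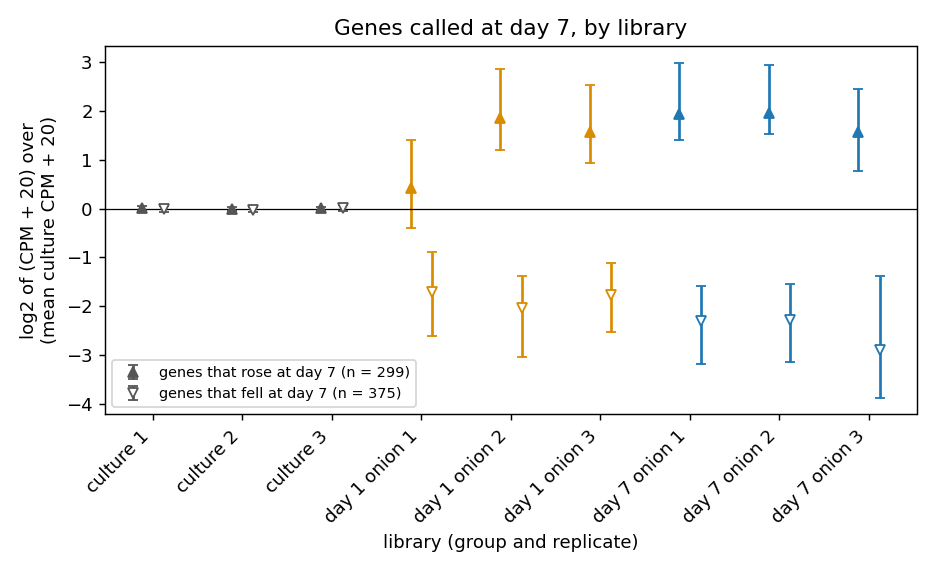
Median log2 ratio of CPM to the culture mean, after adding 20 CPM to both, in each of the 9 libraries for the 299 genes that rose at day 7 (filled upward triangles) and the 375 that fell (open downward triangles), with bars from the 25th to the 75th percentile of genes. In day 1 onion replicate 1 the genes that rose sit at 0.43, below the other 5 onion libraries at 1.58 to 1.96, while the genes that fell sit at -1.71, near day 1 replicate 3 at -1.76.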

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

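The added alternatives (cultures thinned to the median onion depth, 2 libraries left out together, identical gene copies summed, and fitting 2 groups alone or leaving out each library on a fixed gene set) were chosen after seeing the data. The 2 genes printed as risen kept their direction in every setting on both days, and the 2 printed as fallen did so at day 1 in the settings that tested them, while they were not followed at day 7. The correlation of neighbouring locus numbers stayed positive in every setting, from 0.408 to 0.614 at day 1 and from 0.300 to 0.564 at day 7. For day 7 against day 1 it ranged from 0.215 to 0.503. Counts of genes moved more. For day 1 against culture (748), the count was 455 with a replicate block and 85 with every library thinned to 10641 counts. It was 349 against a minimum log2 fold change of 1, and 432 with the cultures thinned to 80691 counts. Limma on FPKM gave 174 and 154 at pseudocounts of 1 and 0.1. DESeq2 gave 1023, limma voom with sample quality weights 822, and the 2 groups fitted alone 638 of the 1966 genes. Without day 1 replicate 1 and day 7 replicate 3 the count was 1089. For day 7 against culture (674), it was 110 thinned to the shallowest library, 1460 of 4204 genes tested with the 2 groups fitted alone and 1166 of the 1966 genes, 1030 with limma voom and sample quality weights, 391 with the minimum fold change, 354 and 276 with FPKM, and 1137 without day 1 replicate 1 and day 7 replicate 3. For day 7 against day 1 (0), it was 120 with DESeq2, 4 and 4 with FPKM, and 13 without those 2 libraries. Leaving out 1 library gave 386 to 1021, 410 to 1121 and 0 to 16 genes in the 3 comparisons on the same genes, and 374 to 1030, 390 to 1132 and 0 to 15 with the filter recomputed. Runs of neighbouring genes held 84 genes at day 1 and 113 at day 7, against 0 and 0 thinned to the shallowest library, 27 and 65 with the cultures thinned, 8 and 26 or 4 and 17 with FPKM, 49 and 50 with the minimum fold change, 49 and 79 with the replicate block, 195 and 134 without a filter, 200 and 134 with 10 counts in every library of 1 group, and 120 and 263 with 2 groups fitted alone and refiltered, or 66 and 152 on the same genes. Leaving out 1 library gave 35 to 126 and 39 to 152 on the same genes, and 39 to 131 and 22 to 156 refiltered. Thinning to the shallowest library left 266 genes to test, and the causes of the other shifts were not tested.

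No pairing by replicate number was seen. The 9 same-number correlations of deviations ranged from -0.225 to 0.101 and 1 of them was above 0.1. Between different numbers they ranged from -0.187 to 0.189. With few counts in the onion libraries and 3 libraries per group, these values cannot show that pairing is absent. With the replicate block, 455, 509 and 0 genes changed in the 3 comparisons. RLE factors moved the median log2 fold change of all genes at day 7 against culture by -0.11 relative to TMM, and the changes given for that comparison are relative to TMM. Under 5 scalings of the edgeR test, 36 to 40 of the 100 most abundant culture genes fell at day 1 and 43 to 47 at day 7, while 1 to 3 and 2 to 3 rose. DESeq2, which differs in test and scaling, gave 52 and 56 that fell and 9 and 5 that rose. Limma voom with sample quality weights gave 69 that fell and 10 that rose on each day. With 1 library left out of the edgeR test, 0 to 7 of these culture genes rose on either day. Tests of gene lists by camera and fry, with their alternatives, and the setting without rRNA, tRNA and ribosomal protein genes were not run, because no identifier could be tied to a name. Depth limits day 7 replicate 3 most, where 1 count is 94.0 CPM.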

Other observations

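The tests in this part on copies of genes, on the depth, mixture and label explanations for day 1 replicate 1, and on neighbouring locus numbers were chosen after the results were seen. The tests of thinned cultures and of other splits were written down before their results, but for thinned cultures the share among all called genes was chosen after the day 1 share among genes still tested, 66.7%, had been seen.

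The annotation behind the files holds duplicated stretches. In 50 pairs of genes, both members had the same counts in all 9 libraries and the same coding length, and in every pair the second member lay among the last locus numbers. The pairs fall into 3 stretches of 21, 19 and 10 pairs, of which the 10 keep the order of the locus numbers and the other 40 mirror it exactly, with rank correlations of 1 and -1. One pair, with a coding length of 2445 bases, ranked 4 among all genes in culture at 9883 CPM for each copy, and would rank 1 at 19767 CPM if the copies were summed. Summing all pairs, an alternative added later, gave 722 genes at day 1 and 680 at day 7 against culture. Levels of these 100 genes, 26 of them tested, are therefore uncertain per copy.

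In day 1 replicate 1, the genes that fell at day 7 lay about as far below culture as in day 1 replicate 3. Genes chosen as higher in culture can lie lower in any library with another profile, so this does not show a shared response. The genes that rose at day 7 were far less raised in this library than in the other onion libraries. Its greater depth does not account for this: with all 6 onion libraries thinned to 10641 counts, its median correlation with the other 5 averaged 0.344 over 20 draws and reached at most 0.362, below the lowest value among those 5, which was at least 0.542, and with the 5 deeper ones at 67487 counts the genes that rose at day 7 had a median log2 ratio of 0.35 in it and of at least 1.55 in the others, as means of 20 draws. A mixture of culture RNA with RNA like that of the other onion libraries would give levels between culture and onion. Instead, 31 tested genes lay more than 4-fold above every culture and every other onion library and took 11.9% of its counts. Any other onion library had at most 1 such gene. Whether culture RNA was mixed with onion RNA of another profile in this library cannot be told from this count. A label exchanged with a day 7 library would give a high correlation with that group, and its highest was 0.430. That value is among those by which the library was seen to stand apart, so it is no separate test of this explanation. A difference between bulbs, or in how far the bacteria had adapted by the time of sampling, may remain as a hypothesis and was not tested. RNA of another bacterium that maps to these genes also stays open. The same limit holds for changes seen in the other onion libraries, since no library taken here as uninoculated onion was compared.

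The gap in depth between cultures and onion libraries could create or shift calls. With the cultures thinned to 80691 counts, 57.4% of the genes called at day 1 and 69.7% of those called at day 7 kept their call and direction, counting genes no longer tested as lost, or 66.7% and 77.4% of those still tested, and all of the called genes that were still tested kept their sign. Thinned cultures are drawn from the same counts, so the kept signs are no evidence by themselves. The kept calls show only that those calls do not need the full depth of the cultures. Thinning cannot show how a low number of bacterial reads affected the onion libraries. Depth, culture medium and the onion environment differ together between the groups, so their contributions stay open. The share of each strain of the mixture in the libraries was not examined.

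Correlated changes of neighbouring locus numbers may reflect genes transcribed together as operons. The lower of the 2 correlations at a distance of 1 was 0.450, and it fell with distance, as that hypothesis needs. Reads shared by overlapping adjacent genes would end at direct neighbours, but the correlation was still 0.167 at a distance of 3, above the shuffled range. A slow trend along the chromosome would persist, but the larger value at a distance of 20 was 0.0112, although at a distance of 50 the day 7 value of 0.0754 was slightly above its shuffled limit of 0.0693. The locus numbers are taken as genome order, which the sources used here do not state.

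Splits of the libraries into 3 and 3 number 10 for each comparison, too few for a share under 0.05. For day 1 against culture the real split gave 748 genes and the highest other split 0, with 1 split reaching the real value. For day 7 against culture the values were 674 and 0, again with 1 split. Every other split against culture mixes cultures and onion libraries within a group. This can widen the fitted spread, so 0 calls there carry little information. For day 7 against day 1 the real split gave 0 genes and the highest other 13. All 10 splits gave at least as many, which a real value of 0 fixes in advance.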
